A study of Escherichia coli with 4 samples.

How the data were processed

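RNA of the Escherichia coli K-12 strain MG1655 and of an isogenic strain with a Tn5 transposon in norR was compared on 4 spotted arrays with 2 colours each. Per the labels, both strains grew in aerobic chemostats limited by 8 mM glycerol, at a dilution rate of 0.1 per hour, an air flow of 1 litre per minute and an oxygen tension held at 40% of air saturation. At steady state the nitric oxide donors NOC-5 and NOC-7 were added at 10 uM each, cells were taken into an RNA stabiliser after 5 min, and total RNA was purified on columns. Each strain was grown in 2 separate chemostat runs. For each run 1 array carried wild-type RNA in Cy3 and mutant RNA in Cy5, and a dye-swap array carried the reverse. The run was therefore the replicate (n = 2), and the arrays of a run were technical repeats of the same pair of RNAs. No array compared cultures without nitric oxide.

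The values analysed were the log2 ratios deposited by the authors in the value table of the series, with 4608 probes and 1 column per array. The scanner, spot filter, background correction, normalization, log base, centring and direction of the ratio are not given in the sources used here. Column medians were -0.0108 for run 1, -0.0347 for its dye swap, -0.0122 for run 2 and -0.0277 for its dye swap, so the columns were near-centred as deposited. A log10 scale was ruled out because the largest value, 5.21, exceeds the log10 range of 4.82 that a 16-bit scanner can record. Natural logs were not ruled out. The values are called log2 as the usual scale of such tables, and every fold change printed rests on that reading. Spot intensities were not used here, so signal over background behind each ratio is unknown and the number of arrays limits the precision.

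Empty cells were treated as not measured. Probes were named through the platform's annotation, which paired 4087 probes with 1 gene symbol, 0 with several and 521 with none. Of the named probes 4086 matched the annotation of assembly ASM584v2 by gene number, and 197 symbols were updated through it. The annotation was used for names only. The probes gave 4038 genes, 49 of them with over 1 probe, which were averaged. With the unnamed probes there were 4559 features, of which 3196 were measured in both runs and tested (2910 genes and 286 unnamed probes). All 4 arrays measured 1156 features, and 391 tested features had values from 1 dye orientation only, so that a dye effect does not cancel in their means.

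The labels give the dye of each strain, and the table does not state whether the dye-swap columns had already been turned to the direction of the others. A rule fixed before the data were examined read the columns by the sign of the correlation between the arrays of a run, and prescribed that the dye-swap columns be multiplied by -1 if the signs were mixed. The correlations were mixed (Pearson r = -0.0704 in run 1 and 0.222 in run 2). By rank they were not mixed, with a Spearman rho of -0.303 in run 1 and -0.0655 in run 2. For correlations below 0 in both runs the rule also prescribed turning. The rule was not followed. The columns were used as deposited, without turning, because all 28 probes with log2 ratios of at least 2 in size on both arrays of a pair had one sign on both (10 of 10 in run 1 and 18 of 18 in run 2). The ground is limited to the largest ratios: at 1.5 or more in size on both arrays the shares with one sign were 82.6% in run 1 and 93.3% in run 2, and at 1 or more they were 53.2% (41 of 77) and 73.2% (52 of 71). This departure was made after the values had been seen, those of norV, norW and the flagellar genes included. The reading that the rule prescribed is kept among the alternatives, and it changes most of the results. The direction, norR mutant over wild type, is likely and not settled. Its basis is the known role of NorR as activator of norVW, together with low values of these genes on each array that measured them, so their fall is no separate check of the direction. If the ratio runs the other way, every "higher" reads "lower" and the reverse.

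Each array was centred on its median, the arrays of a run that measured a feature were averaged, and the run values were fitted with an intercept in limma 3.58.1 under R 4.3.3, with empirical Bayes moderation (prior degrees of freedom 3.86), two-sided. A feature was called at a Benjamini-Hochberg adjusted p under 0.05. Gene lists, 29 in number, were fixed before the data were examined. The 27 with at least 3 tested members were tested with camera, two-sided, at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists, and the others are given as single genes. The estimated correlation used as an alternative rests on a single residual degree of freedom. An exact sign-flip test over 2 runs cannot give a two-sided p under 0.5, so no such test was used, and p-values rest on the spread shared across genes in limma. The count of features on one side on all 4 arrays was set beside the same count under the 3 other sign patterns of the arrays (run against run, dye against dye, and their product), which carry no strain effect if the dye-swap columns had been turned before deposit; if not, the pattern by dye is that of the strains. No regrouping of samples was possible with 2 runs.

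Genes were named by a rule fixed before the data were examined: norR, norV, norW and the measured genes of the NsrR regulon; up to 10 genes on each side with the largest means among calls with one sign on all 4 arrays, filled with uncalled genes of one sign on all 4 arrays; and the 2 highest and 2 lowest members of each list described. The other called features, flhD and flhC, flagellar genes measured in 1 run only, motility genes outside the lists, and genes called in the fit with a dye term were named after their values were seen.

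The run numbers of the labels pair the arrays by chemostat run. Over features measured on all 4 arrays, the deviations of the paired arrays from the means of their dye orientations correlated at 0.235. A fit of the 4 arrays with the run as a block estimated a within-run correlation of -0.498, the arrays of a run differing in dye orientation. Other alternatives were no centring, scaling and quantile normalization of the ratios, turned dye-swap arrays, features measured on all 4 arrays, and single probes. Another left out features with paired arrays over 1 log2 unit apart, and kept features without a complete pair. The rest were each dye orientation alone, each run alone, arrays as independent samples, a dye term, robust moderation, other thresholds, an estimated correlation and fry. Added after the data had been seen were features measured in both orientations, named genes only, and values read as natural logs.

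The procedure was tested on simulated data with gene-specific spread and the dye effect of these arrays. For the comparison of the strains over 3196 features, it recovered 13.6% of features changed 2-fold, 86.8% of those changed 4-fold and 98.8% of those changed 8-fold, and 4.36% of its calls were false. With a dye term over 2805 features it recovered 67.5%, 99.1% and 100% at the same sizes, with 6.89% false calls. The simulation held array noise and a dye effect but no added spread between runs, so it does not test how spread between cultures would add false calls.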

Results

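The series asked how a norR mutant of E. coli differs in transcript levels from its wild type under brief nitric oxide stress in air. NorR is a transcription factor that senses nitric oxide and activates the norVW operon. Both strains were exposed for 5 min to NOC-5 and NOC-7, compounds that release nitric oxide on dissolving, in glycerol-limited chemostats, and were compared directly on 4 arrays from 2 chemostat runs. In 1 group of arrays the wild type was labelled with Cy3 and the mutant with Cy5 (1 array per run), and in the other the dyes were swapped (1 array per run). Of 4608 probes, 2907 had a value on the run 1 array (63.1%), 2886 on its dye swap (62.6%), 58.8% of them on the run 2 array, and 3100 on its dye swap (67.3%). Only 1157 probes had a value on all 4 arrays, and 197 had none. Values below are log2 ratios of norR mutant over wild type, given as the mean of the runs ± SD (n = 2 runs). The log base is assumed and the direction is likely, from the known dependence of norVW on NorR. The dye-swap columns were read as already turned to the direction of the others, against a rule set before the data were examined, and values under the rule's reading stand beside the main results. Where a test is given from 1 run alone, it sets that run's ratio against the technical spread between its dye-swap arrays (n = 1 run) and says nothing of the spread between cultures. A value from 1 run alone covers only features on both arrays of that run, so the members of a list differ from those of the main test. Fits with a dye term or with arrays as units also count dye swaps of the same RNAs toward the spread.

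norV and norW were lower in the mutant than in the wild type. norV (b2710), which encodes the flavorubredoxin that reduces nitric oxide, was 13.2-fold lower, at -3.73 ± 0.34 (limma, adjusted p = 0.0178), and lay below 0 on the 3 arrays that measured it. norW (b2711), which encodes the reductase that passes electrons to NorV, was 8.02-fold lower, at -3.00 ± 0.13 (adjusted p = 0.0186), and lay below 0 on all 4 arrays. These were the lowest means of all 3196 features tested, and both genes also passed when adjusted over the list alone. The transcript of norR itself (b2709), the gene that carries the transposon, had a mean of -1.17 ± 0.28 and did not pass the test over all genes (unadjusted p = 0.00398 and adjusted p = 0.184 in limma). Its values were -1.37 and -1.91 on the arrays with the wild type in Cy3 and -0.04 on the dye swap of run 2, and on the first pair alone it passed (-1.64, adjusted p = 0.0162). The place of its probe relative to the transposon is not given in the sources used here, so the probe does not check the labels. None of the 7 tested neighbours of norR passed, and 0 passed when adjusted over the list alone (list mean -0.20, camera adjusted p = 0.219). From run 1 alone that list was at -0.35 over the members on both of its arrays, against -0.24 in run 1 over all 7. With the dye-swap arrays turned, norV was at -1.63 (adjusted p = 0.251) and norW at -0.20 (adjusted p = 0.653), and neither passed. From run 1 alone norW was at -3.10 with an adjusted p of 0.0569.

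Genes of the flagellum and of chemotaxis were higher in the mutant, and they made up 13 of the 22 features called on run means. Their share was smaller in other fits: 27 of 84 with a dye term, 29 of 78 with the run as a block and 14 of 49 over features on all 4 arrays. Of 35 tested members of that list 13 were higher and 0 lower, 34 had a mean above 0, and the list mean was 2.18 (2.03 in run 1 and 2.32 in run 2). When adjusted over the list alone, 32 were higher. The highest values were those of fliS, the flagellin export chaperone, at 4.59 ± 0.47 (24.1-fold, adjusted p = 0.0178), and of fliA, the flagellar sigma factor, at 4.35 ± 0.15 (20.4-fold, adjusted p = 0.0178). flgM, which encodes the anti-sigma factor of FliA, was at 3.38 ± 0.56 (adjusted p = 0.026). Genes of the rod, the hook and the hook-filament junction that passed were flgD at 3.71, flgE at 3.38, flgC at 3.31, flgG at 3.29, flgK at 2.98 and flgL at 2.75. Also higher were fliZ at 3.58, the chemoreceptor gene trg at 2.77, the chemotaxis kinase gene cheA at 2.49 and fliH, of the flagellar export apparatus, at 2.10. fliF, of the basal ring, had a mean of 2.19 and flgB, of the rod, 2.19, without passing (adjusted p = 0.0973 and 0.0553). The lowest members were fliI at -0.47 ± 0.01 and fliT at 0.36 ± 0.03. The genes of the master regulator, flhD and flhC, had means of 1.54 ± 0.10 and 1.44 ± 0.04 and did not pass (adjusted p = 0.0818 and 0.0877). Both passed in limma with the run as a block (adjusted p = 0.00462 and 0.000924) and with a dye term (0.00792 and 0.000943). These fits take the 4 arrays as units, so they add nothing to the 2 runs. The block fit used a within-run correlation of -0.498 and called more features than arrays taken as independent samples (78 against 45). A further 10 members were measured in 1 run only and were not tested; all lay above 0, the highest being the chemoreceptor gene tar at 4.39 and the motor gene motB at 3.76.

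In the list test the flagellar genes were shifted up against the other genes (camera, adjusted p = 5.44e-45). For every list, this test sets its genes against the other genes at the preset correlation. Its p-value does not measure how well a shift repeats over the 2 runs. With an estimated correlation, which rests on a single residual degree of freedom, the adjusted p of the flagellar list was 0.903 and no list passed. A failure with it therefore does not tell an unshifted list from a shifted one. With a dye term, 27 of the 31 flagellar genes that could be tested were higher and 0 lower. With the dye-swap arrays turned, 1 was higher and 2 were lower, and the list passed in the opposite direction, with a mean of -0.50 (camera, adjusted p = 0.0196). The higher gene was flgC and the lower ones fliZ and flgE. flgC and fliZ were measured in 1 dye orientation only, so turning could not change the size of their means.

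**Figure D1:**
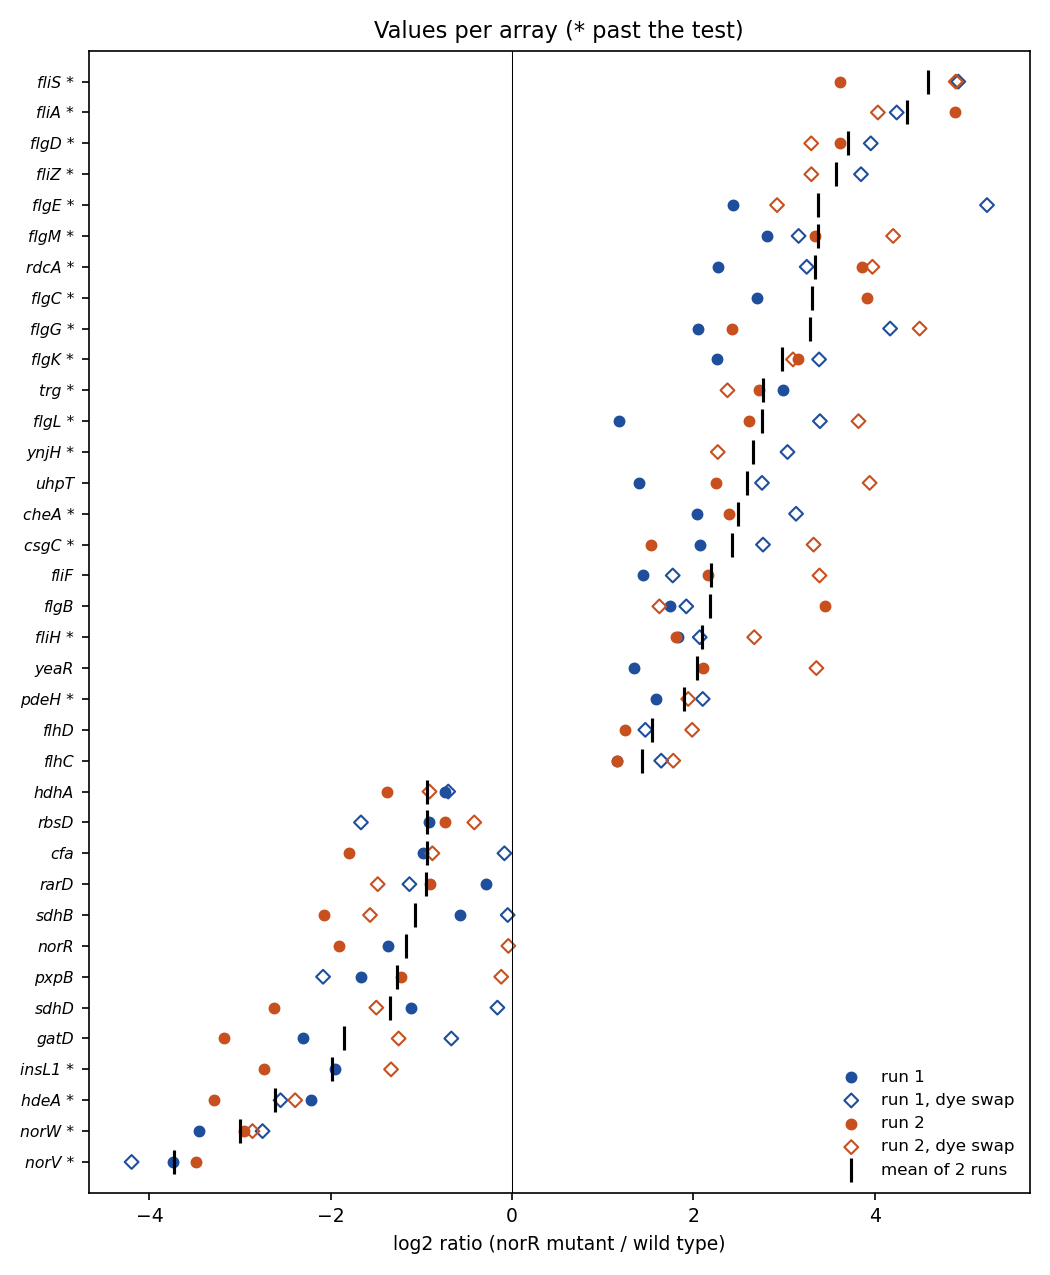
Log2 ratio of norR mutant over wild type (x axis) of each named gene (y axis) on each array; filled circles are arrays with the wild type in Cy3, open diamonds dye swaps, blue run 1, orange run 2, bars the mean of the runs, and a star marks an adjusted p under 0.05. norV, norW and hdeA lie below -2 on each array that measured them, and fliS and fliA above 3.

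In all, 22 of 3196 features differed between the strains at an adjusted p under 0.05, 18 higher and 4 lower in the mutant, of which 21 were named genes. Outside the flagellar list, the genes that were higher were rdcA, named crfC on the array, at 3.34 ± 0.82 (adjusted p = 0.0435), ynjH at 2.66 ± 0.54 (adjusted p = 0.0435), csgC, of curli assembly, at 2.43 ± 0.01 (adjusted p = 0.026), and pdeH, which encodes a phosphodiesterase of cyclic di-GMP that acts on motility, at 1.90 ± 0.07 (adjusted p = 0.0479). The unnamed probe 1.3.16.11, measured on 1 array per run, was also higher, at 1.96 ± 0.05 (adjusted p = 0.0435). uhpT, the hexose phosphate transporter gene, had a mean of 2.59 ± 0.72 and did not pass (adjusted p = 0.0553). Below norV and norW in size, the genes that were lower were hdeA, a periplasmic acid chaperone gene, at -2.61 ± 0.32 (adjusted p = 0.0273), and insL1 at -1.99 ± 0.06 (adjusted p = 0.0435). insL1 belongs to an insertion sequence present in several copies, so its value is uncertain as that of 1 gene. Among uncalled genes below 0 on all 4 arrays the lowest were gatD, of galactitol catabolism, at -1.85 ± 0.52 (adjusted p = 0.0877), the succinate dehydrogenase genes sdhD at -1.35 ± 1.01 and sdhB at -1.07 ± 1.07, and pxpB, of 5-oxoprolinase, at -1.27 ± 0.85. In run 2 sdhD was at -2.06 and sdhB at -1.82, and in run 1 they were at -0.64 and -0.31; against the technical spread of run 2 alone the adjusted p was 0.000213 and 0.00227. They were followed by rarD at -0.95, the cyclopropane fatty acid synthase gene cfa at -0.94, and rbsD and hdhA at -0.93 each.

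Of the 22 features called, 9 were measured on all 4 arrays, 9 on 3 and 4 on 2, and fliZ, flgC and ynjH had values in 1 dye orientation only. The count was 84 (60 higher and 24 lower) with a dye term over 2805 features, which kept all 19 calls it could test, 78 (58 and 20) with the run as a block, and 49 (33 and 16) over the features on all 4 arrays. It was 43 from run 2 alone and 1 from run 1 alone, where the spread is that between dye orientations and norV alone of 13 testable calls was kept. Genes with an adjusted p under 0.05 against the technical spread of run 2 alone but not in the mean included, among others, uhpT (3.10), fliF (2.78), yeaR (2.73), flgB (2.54), flhD (1.62), flhC (1.47), sdhC (-3.12), gatD (-2.21), sdhD (-2.06) and sdhB (-1.82). With the dye-swap arrays turned the count was again 22, of which 4 were called in both readings: flgC in the same direction, and fliZ, flgE and ynjH in the opposite one. For flgC, fliZ and ynjH the size and direction were fixed by the missing arrays, since turning cannot change the size of a mean from 1 dye orientation. Their calls therefore do not compare the readings.

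Genes of acid resistance were lower in the mutant as a group. Of 10 tested members 1, hdeA, was lower, 5 were lower when adjusted over the list alone, and all 10 had means below 0, with a list mean of -1.01 (-1.06 in run 1 and -0.96 in run 2; camera, adjusted p = 2.1e-07; adjusted p = 0.903 with an estimated correlation). hdeB, of the same operon as hdeA, had a mean of -2.21 ± 0.57 and did not pass (adjusted p = 0.0598), and the highest members were mdtE at -0.03 and yhiD at -0.13. The list of general stress genes under RpoS, the stationary-phase sigma factor, had a mean of -0.27 over 23 genes, 0 of them called over all genes or adjusted over the list alone (camera, adjusted p = 0.0055; adjusted p = 0.903 with an estimated correlation). Its lowest members were cfa at -0.94 and wrbA at -0.76, and its highest yodC at 0.55 and treA at 0.24. The heat shock list had a mean of -0.32 over 13 genes with 0 calls in either adjustment, that over the list alone included (camera, adjusted p = 0.0055; adjusted p = 0.903 with an estimated correlation). The chaperonin genes groL at -0.86 and groS at -0.70 were its lowest members and htpX at 0.07 and lon at 0.00 its highest. On the dye swaps alone the heat shock list was at -0.14 (adjusted p = 0.69), against -0.69 (adjusted p = 0.00214) on the other arrays, and the RpoS list passed in neither orientation alone (adjusted p = 0.232 and 0.0837). None of these lists passed with the dye-swap arrays turned (adjusted p = 0.861 for acid resistance, 0.861 for RpoS and 0.285 for heat shock).

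Genes of glycerol metabolism, the pathway of the limiting carbon source, were shifted up as a list, with a mean of 0.58 over 13 genes (0.75 in run 1 and 0.41 in run 2; camera, adjusted p = 0.000495; adjusted p = 0.903 with an estimated correlation). None passed over all genes, 6 were higher when adjusted over the list alone, and 6 of 12 were higher with a dye term. The highest members were glpB, of the anaerobic glycerol-3-phosphate dehydrogenase, at 1.34 ± 0.48, and glpD, the aerobic enzyme, at 1.25 ± 0.92; the lowest were glpE at -0.29 and glpR, the repressor gene, at -0.03. With the dye-swap arrays turned the list mean was -0.23 and the list did not pass (adjusted p = 0.32).

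Lists of central metabolism and sulfur metabolism were shifted down with no called member. The tricarboxylic acid cycle list had a mean of -0.51 over 14 genes (camera, adjusted p = 0.0102; adjusted p = 0.927 with an estimated correlation), and the aerobic respiration list -0.27 over 34 genes (adjusted p = 0.04; adjusted p = 0.927 with an estimated correlation). The runs differed in both: the first list was at -0.02 in run 1 and -1.0 in run 2, and the second at 0.09 and -0.64. sdhC, of succinate dehydrogenase, was the lowest gene of both lists at -1.92 ± 1.69, followed by sdhD, and the highest were sucC at 0.19 and sucB at 0.05 in the first and atpC at 0.36 and nuoF at 0.31 in the second. The list of cysteine synthesis and sulfate assimilation had a mean of -0.27 over 20 genes (adjusted p = 0.00559; adjusted p = 0.903 with an estimated correlation; -0.11 in run 1 and -0.44 in run 2), from cysK at -0.74 and ssuE at -0.74 to sbp at 0.10 and ssuD at 0.42. The methionine list had a mean of -0.35 over 11 genes (adjusted p = 0.0214; adjusted p = 0.903 with an estimated correlation), from metK at -0.92 and metR at -0.88 to metH at 0.14 and metJ at 0.63. The hydrogenase list had a mean of -0.23 over 18 genes (adjusted p = 0.0214; adjusted p = 0.903 with an estimated correlation), from hybO at -0.72 and hycF at -0.69 to hybC at 0.06 and hyaF at 0.70. In all 5 lists 0 genes passed when adjusted over the list alone. Over members on both arrays of a run, the sulfur list was at -0.19 and the methionine list at 0.07 from run 1 alone. The hydrogenase list was at 0.17 from run 2 alone. Over all tested members the methionine list was at -0.17 in run 1 and -0.52 in run 2, and the hydrogenase list at -0.20 and -0.27. With the run as a block the hydrogenase list did not pass (camera on that fit, adjusted p = 0.296). None of the 5 passed on the dye swaps alone. With the dye-swap arrays turned, of these 5 only the aerobic respiration list passed (-0.33, adjusted p = 0.000556). Before turning, over members on both arrays of an orientation, it was at -0.72 with the wild type in Cy3 and 0.09 on the dye swaps. Its pass on turning reflects that difference between dye orientations and does not repeat the main result.

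**Figure D2:**
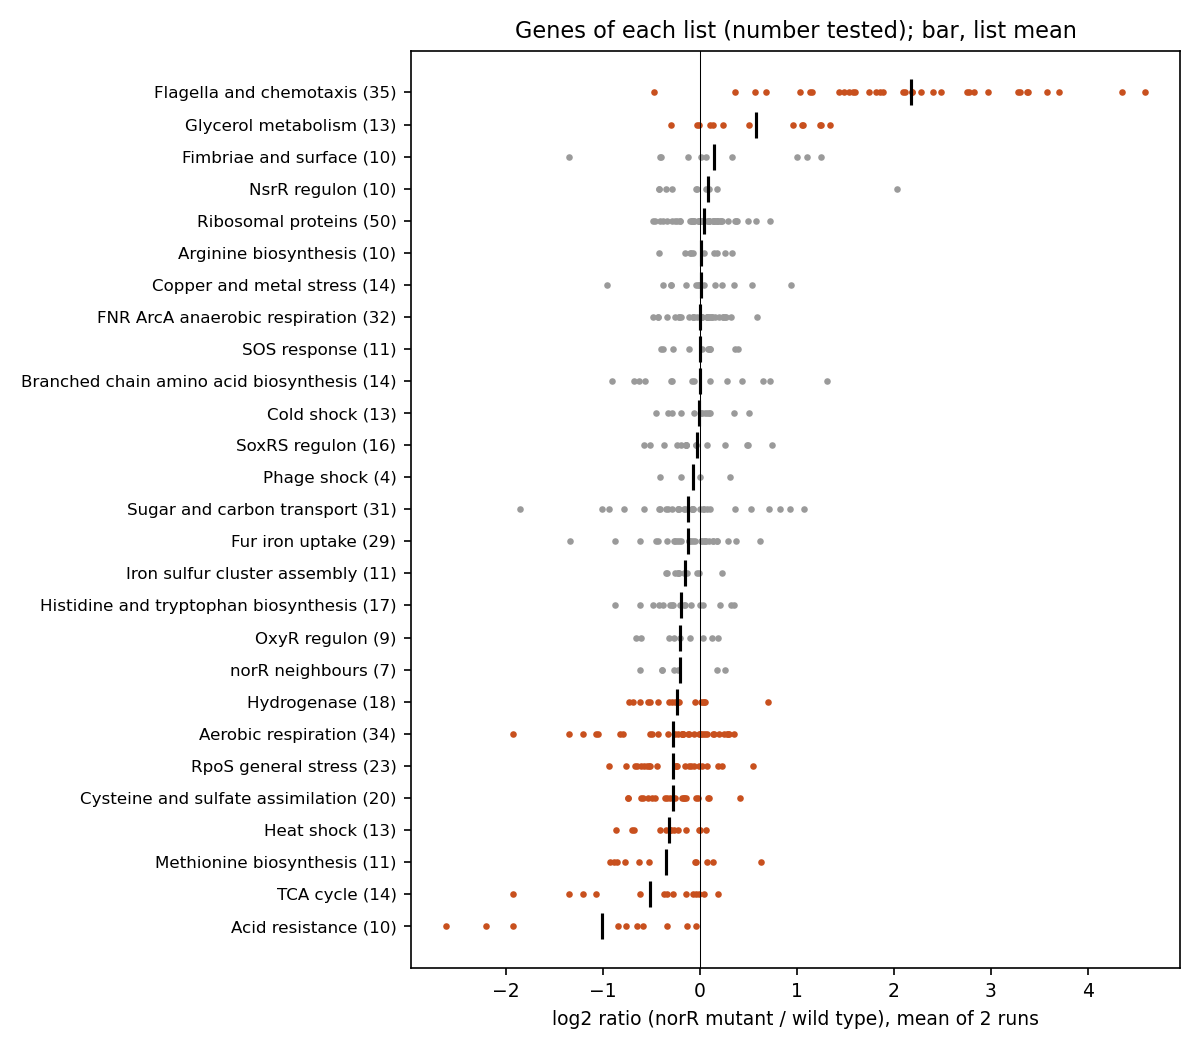
Mean log2 ratio of norR mutant over wild type (x axis) of each tested gene in the lists with at least 3 tested members (y axis, number tested in parentheses); points are genes, bars list means, and orange marks lists with a camera adjusted p under 0.05 at the preset correlation. The flagellar list, with a mean of 2.18, and the acid resistance list, with a mean of -1.01, lie at the ends.

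The genes of the other nitric oxide regulon, under the repressor NsrR, did not pass in either direction. Of 10 tested members 0 passed over all genes, and 1, yeaR, was higher when adjusted over the list alone. yeaR had a mean of 2.04 ± 0.98 (adjusted p = 0.17) and was higher in the fit with a dye term (2.54, adjusted p = 0.000437), the adjusted p ranging from 7.13e-08 to 0.659 over the alternatives. hmp, the flavohaemoglobin gene, was at -0.35 ± 0.66, hcp, the hybrid cluster protein gene, at -0.42 ± 0.48 and hcr, its reductase gene, at -0.42 ± 0.02. ytfE, of iron-sulfur centre repair, was at -0.28 ± 0.14. tehA was at 0.07, tehB at -0.04, yoaG at 0.10, ygbA at -0.03 and pdxI, the listed ydbC, at 0.18. The list mean was 0.09, the median was -0.03, and the test pointed down (camera, adjusted p = 0.857).

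The other lists did not pass, and in each of them 0 genes passed over all genes. For stress regulons and metals, the means and camera adjusted p were -0.12 and 0.219 for iron uptake under Fur, -0.15 and 0.161 for iron-sulfur cluster assembly, -0.03 and 0.738 for SoxRS, -0.20 and 0.161 for OxyR, 0.00 and 0.978 for SOS, -0.07 and 0.784 for phage shock, -0.01 and 0.932 for cold shock, and 0.01 and 0.932 for copper and metal stress. For metabolism they were 0.01 and 0.934 for anaerobic respiration under FNR and ArcA, 0.01 and 0.934 for arginine, 0.00 and 0.784 for branched-chain amino acids, -0.19 and 0.0658 for histidine and tryptophan, and -0.12 and 0.285 for sugar and carbon transport. The ribosomal protein list was at 0.04 (adjusted p = 0.784) and the list of fimbriae and surface structures at 0.15 (adjusted p = 0.536). Over its members on both arrays of a run, the fimbrial and surface list was at 0.59 from run 1 alone and 0.30 from run 2 alone. Over its 10 tested members it was at 0.25 in run 1 and 0.05 in run 2. When adjusted over the list alone, 3 fimbrial and surface genes were higher and 1 lower, 1 transport gene was lower, and 0 genes passed in the other lists of this paragraph. Mean, median and test differed in sign for the SOS, cold shock, copper, anaerobic respiration, arginine and branched-chain lists.

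The runs resembled each other most for the genes with large differences. Across 3196 features the run values had a Pearson r of 0.395 and a Spearman rho of 0.167, and across the 1156 features on all 4 arrays 0.561 and 0.134; features are not independent replicates. Single arrays of the same dye orientation but different runs had a Pearson r of 0.541 and 0.61 (Spearman rho 0.466 and 0.482). Arrays of the same run but opposite orientation had a Pearson r of -0.0704 and 0.222 (Spearman rho -0.303 and -0.0655). On all 4 arrays 31 features, among them norW, hdeA, flgM, flgG and flgK, lay on one side with a mean difference of at least 2-fold, 25 higher and 6 lower in the mutant. The other sign patterns of the arrays gave 21 such features by dye orientation, 0 by run and 0 by their product. If the dye-swap columns had not been turned before deposit, the pattern by dye orientation would be that of the strains. The largest dye component was 1.43 and the largest strain mean 3.38. Without the fold limit, 146 of the 1156 features lay on one side for the strain, 396 by dye orientation, 79 by run and 67 by their product. Chance gives 12.5% of features for each pattern only if the signs of the 4 arrays are independent. The count by dye orientation shows that they were not, so this share does not give the count due to chance here. The strain count was close to that share, and above the counts by run and by their product.

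**Figure D3:**
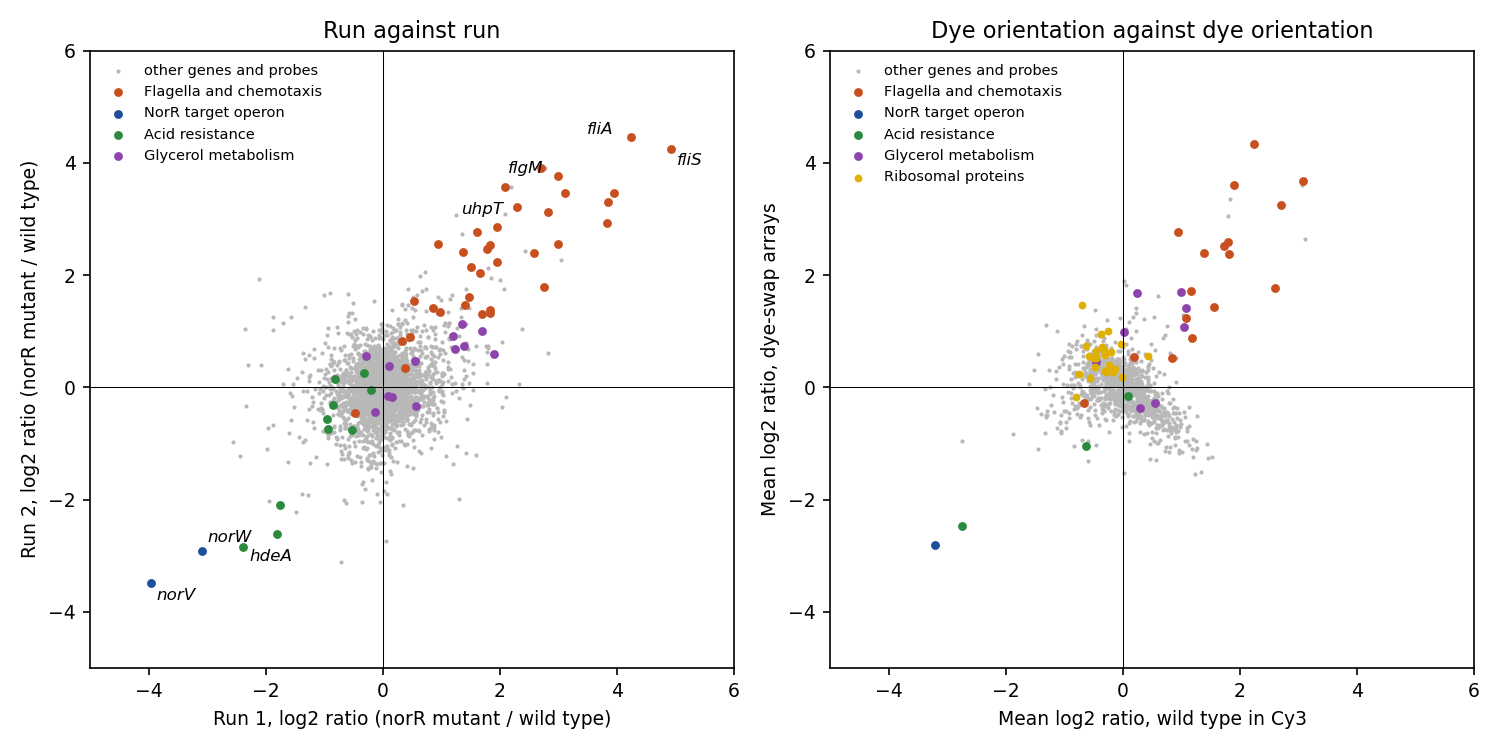
Left, log2 ratio of norR mutant over wild type in run 1 (x axis) and run 2 (y axis) for 3196 features; right, mean log2 ratio on the arrays with the wild type in Cy3 (x axis) and on the dye swaps (y axis) for the 1156 features on all 4 arrays. Points are features, coloured by list; flagellar genes and norV, norW and hdeA lie along the diagonal, and the ribosomal protein genes lie mainly above 0 on the dye swaps and below 0 on the other arrays.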

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

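The tests in this part were chosen after the results had been seen, except that of a second strain difference, which rests on the design. In the fit with a dye term, 82 of 2805 features differed between the dye orientations at an adjusted p under 0.05, 56 with the higher ratio where the mutant carried Cy5 and 26 with the lower, and this difference between the arrays of opposite labelling is what singled them out. With a strain effect in dye-swap columns left unturned, large ratios would have opposite signs on the arrays of a pair. norW had a dye component of -0.1975 beside a mean of -3.00. All 28 probes with values of at least 2 in size on both arrays of a pair had one sign. The signs of these probes were the ground for the reading used, which was chosen with the values of norW seen. Neither is therefore a separate test of that reading. Both cover the largest ratios, norW and flagellar genes among them, and take them as strain effects. At 1 or more in size, 41 of 77 probes in run 1 and 52 of 71 in run 2 had one sign. Smaller ratios therefore do not settle the reading. A dye bias that follows transcript abundance may account for part. The ribosomal protein genes, known as abundant transcripts, had a median dye component of -0.4417, and 25 of 25 lay below 0, although 1 of 47 passed singly. Their side is that of the 26 features with the lower ratio, and opposite to that of the other 56. With the dye-swap columns turned these values would be a strain effect, so they do not tell the readings apart. Spot intensities were not used here, so the dependence on brightness itself stays open, and no biological explanation was tested.

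The flagellar and chemotaxis list had a mean of 2.18, or of -0.50 with the dye-swap arrays turned. With the columns read as already turned, 30 of the 31 genes measured in both orientations lay above 0 in each (list means 1.81 and 2.47). That reading was chosen from large ratios with one sign on both arrays of a pair, flagellar genes among them. The count of 30 therefore cannot exclude dye bias. Under the same reading, a change in 1 run only is argued against by 34 of 35 genes above 0 in both runs. More transcript of the master regulators may stand behind the shift, since flhD and flhC were at 1.54 and 1.4363. Neither passed the test over all genes on run means. Both passed in limma with the run as a block (adjusted p = 0.00462 and 0.000924) and with a dye term, fits that take the arrays as units and add no runs. The values do not tell cause from consequence. A second difference between the strains, such as an insertion element upstream of flhDC that differs between MG1655 stocks, cannot be told apart from loss of norR, because the design holds 0 arrays of a second norR mutant or a complemented strain.

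The calls of fliZ, flgC and ynjH rest on 1 dye orientation, where a dye bias does not cancel. The largest dye component over features on all 4 arrays was 1.43 and the smallest of these 3 calls was 2.66. No feature with a measured dye component therefore reached their size, if the columns are read as already turned. The dye component of these 3 genes themselves was not measured, so the comparison cannot exclude dye bias as their cause.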

How the results depend on the processing

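Values read as natural logs, features in both orientations and named genes only were settings chosen after the data had been seen; the others were fixed before. Turning the dye-swap arrays is the reading that the rule fixed beforehand prescribed, and it changes most results. norV was at -1.63 and norW at -0.20, neither past the test. In place of 10 lists 5 passed (0 up and 5 down), the flagellar and aerobic respiration lists among them. The 22 calls (12 higher, 10 lower) held 4 of those reported, 1 in the same direction and 3 in the opposite one. Of these, flgC, fliZ and ynjH rest on 1 dye orientation, so their sizes could not change on turning. The following means changed sign under it: ygbA 0.10, yoaG -0.13, pdxI -0.13, tehB 0.29, fliS -2.78, fliA -1.91, flgD -1.90, fliZ -3.58, flgE -2.16, flgM -0.30, rdcA -0.27, flgG -1.05, flgK -0.27, flgL -0.86, ynjH -2.66, uhpT -0.76, csgC -0.62, fliF -0.39, fliH -0.27, pdeH -1.10, rarD 0.36, rbsD 0.11, nuoF -0.56, atpC -0.26, sucB -0.43, glpE 0.29, glpR 0.33, glpD -0.17, glpB -0.35, metH -0.0096, metJ -0.14, ssuE 0.40, sbp -0.35, lon -0.39, htpX -0.043, treA -0.33, hdeB 1.07, yhiD 0.13, mdtE 0.11, hyaF -0.70, fliT -0.17, flhD -0.92, flhC -0.28, the unnamed probe 1.3.16.11 at -0.037, the glycerol list -0.23 and the flagellar list -0.50. For features on all 4 arrays this follows from the construction, since turning exchanges their strain and dye components. For features on fewer arrays the exchange is incomplete. With 1 dye orientation only, turning keeps the size of the mean and either leaves or reverses its sign.

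The count of 22 calls became 49 over features on all 4 arrays, 8 with pairs differing by over 1 left out, 67 on arrays with the wild type in Cy3, 196 on the dye swaps, 78 with the replicate block, 45 with arrays as independent samples, 84 with a dye term (these 3 count dye swaps of the same RNAs toward the spread), 47 at an adjusted p under 0.1 and 120 at an unadjusted p under 0.05 with 2-fold. Leaving out a run gave 1 to 43, against the technical spread between the dye swaps of the run left. In the self-test, which held no added spread between runs, the dye term also recovered more 2-fold changes than run means did. The self-test therefore does not tell why the counts differ, and the cause was not tested. It stayed within 1.5 times at 33 without centring, 26 and 27 with scaled and quantile-normalized arrays, 21 for single probes, 22 with robust moderation, 17 over features in both orientations and 30 for named genes only. The replicate block changed no call of norR, norV or norW and left 9 lists, with the hydrogenase list no longer past the test.

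The count of 31 features at least 2-fold on one side became 14 with pairs differing by over 1 left out, 137 on arrays with the wild type in Cy3, 140 on the dye swaps, 69 at 1.5-fold, 18 at 3-fold, 59 read as natural logs, and 56 to 104 leaving out a run, where fewer arrays have to share a side. The 10 lists became 4 on the dye swaps. They became 0 with an estimated correlation, which rests on a single residual degree of freedom, 0 with fry in its directional form and 0 in its mixed form. The Pearson r between runs, 0.395, was 0.561 on all 4 arrays, 0.542 on arrays with the wild type in Cy3 and 0.607 on the dye swaps. norR passed only on arrays with the wild type in Cy3 (-1.64), with adjusted p between 0.0162 and 0.466 over the alternatives. norW ranged from -3.10 to -2.91 leaving out a run, and did not pass from run 1 alone. norV kept its call in each setting that could test it except turning. Adjusted p over the alternatives ranged from 1.67e-05 to 0.251 for norV and from 6.88e-18 to 0.653 for norW. Of the other genes that the fixed rule or a call led to be named, with flhD and flhC, 17 passed newly with a dye term and 15 with the replicate block, and 11 no longer passed from run 1 alone; without centring or with robust moderation none lost its call, with scaled arrays the unnamed probe did, and with quantile normalization 2 genes did. The cause of these changes was not tested.

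Among other settings, means that changed sign were nuoF at -0.033 with a dye term and -0.015 with the replicate block, mdtE at 0.013 with scaled arrays, and lon at -0.018 without centring. On arrays with the wild type in Cy3 they were ygbA 0.073, yoaG -0.024, sucB -0.39, glpR 0.30, lon -0.39 and mdtE 0.082. On the dye swaps they were hmp 0.070, tehA -0.75, the aerobic respiration list 0.094 and the NsrR list -0.090. The NsrR list was at -0.052 over features on all 4 arrays and -0.081 with pairs differing by over 1 left out, and the hydrogenase list at 0.037 on all 4 arrays. Leaving out a run gave sucB -0.40 to 0.49, metH -0.062 to 0.35, mdtE -0.33 to 0.26, hmp -0.82 to 0.12, yoaG -0.036 to 0.24, tehA -0.043 to 0.17, glpR -0.15 to 0.094, lon -0.028 to 0.035 and hybC -0.11 to 0.23. It gave -0.23 for nuoF, -0.064 for treA and -0.036 for yodC, each with 1 run that could be left out. For lists it gave hydrogenase -0.13 to 0.17, aerobic respiration -0.73 to 0.087, the tricarboxylic acid cycle -1.08 to 0.029, methionine -0.52 to 0.066 and NsrR -0.040 to 0.15. Leaving out a run also changed the members of a list. Over the same tested members, the hydrogenase, methionine and tricarboxylic acid cycle lists were below 0 in each run, and the NsrR list was above 0 in each. The aerobic respiration list still differed in sign between the runs. With pairs differing by over 1 left out, the tricarboxylic acid cycle list (-0.36, adjusted p = 0.104) and the aerobic respiration list (-0.24, adjusted p = 0.149) did not pass, nor did the methionine list on all 4 arrays (-0.19, adjusted p = 0.667). On arrays with the wild type in Cy3 the glycerol (adjusted p = 0.074), methionine (0.198), RpoS (0.0837) and hydrogenase (0.332) lists did not pass, and on the dye swaps the tricarboxylic acid cycle (0.618), methionine (0.837), heat shock (0.69), RpoS (0.232), hydrogenase (0.86) and aerobic respiration (0.847) lists did not. The cysteine and sulfate list, at -0.50 to -0.19, did not pass from run 1 alone, on all 4 arrays (adjusted p = 0.145) or on the dye swaps (adjusted p = 0.37); the fimbrial and surface list was at 0.50 on all 4 arrays (adjusted p = 0.0502). The cause was not tested. Signal over background is not known here, and 32.7% to 41.2% of the probes lack a value on an array, so a gene without a value has no limit on its change.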

Other observations

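The fit with a dye term, a fixed alternative that takes out the difference between dye orientations, called 84 features. It treats the 4 arrays, and not the 2 runs, as units, so that dye swaps of the same RNAs count toward the spread. The genes below were named after their values were seen, and of them only csgC and hdeA are among the 22 calls on run means. Of surface structures, fimA, the major subunit of type 1 fimbriae, was higher in the mutant at 1.11 (adjusted p = 0.00676), and of curli genes csgC was at 2.43 (adjusted p = 5.54e-05) and csgG, the export pore, at 1.09 (adjusted p = 0.0371). crl, which encodes a protein that helps RpoS bind RNA polymerase, was lower at -1.44 (adjusted p = 0.0116). Among transport genes oppA, for oligopeptide binding, was higher at 1.91 (adjusted p = 0.000356), uhpT, for hexose phosphates, at 2.59 (adjusted p = 0.000163), and malE, for maltose binding, at 0.83 (adjusted p = 0.0402). The porin gene nmpC was lower at -0.93 (adjusted p = 0.0387), as was adhP, an alcohol dehydrogenase gene, at -1.11 (adjusted p = 0.0371). Of acid resistance genes hdeA, hdeB and gadC, the glutamate antiporter gene, were lower at -2.61, -2.12 and -1.82. With the glycerol genes glpA, glpB, glpC, glpD, glpQ and glpT higher at 0.96 to 1.34, these calls rest on 2 runs and on the dye-swap columns being read as turned.

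Motility genes outside the fixed flagellar list were collected after the flagellar values had been seen. Of 7 such genes measured, 6 had a mean above 1, with a median of 1.90, whereas 2.78% of all tested features had a mean above 1. They were rdcA at 3.34, ynjH at 2.66, ymdA at 2.16, pdeH at 1.90, rdcB at 1.41 and flxA at 1.14; yecR was lower in size at 0.55. rdcA, ynjH and pdeH passed the test over all genes and prompted the list, so these values do not test whether genes of the flagellar regulators share a shift. rdcA was at -0.27, ynjH at -2.66 and pdeH at -1.10 with the dye-swap arrays turned.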
